A study of Mus musculus with 16 samples.

How the data were processed

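RNA was measured in mouse embryoid bodies at day 6 of SFEBq differentiation in 4 groups of 2 biological duplicates, each with 2 technical runs, which makes 16 samples. RNA was isolated with an RNeasy kit and DNase treatment, and libraries followed the TruSeq protocol, per the labels' protocols. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools 1.5, deepTools and Cufflinks 2.2.1 were used with the mouse build mm10. The gene annotation and the strand setting are not given in the sources used here, so antisense partners and overlapping genes cannot be told apart. Both tables list the same 28432 loci with 16 columns of values used, and the FPKM table gives their mm10 coordinates and, for all but 5143, a gene name.

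Per the file headers, the deposited count table holds estimated counts of fragments per locus, and the values show that the authors' software had multiplied them by a single factor per library. The value of 1 fragment lay between 0.630 and 1.29 by column, and 92.9% to 93.9% of values were whole multiples of it within a tolerance of 0.02 fragments. This factor was divided out, the technical columns were summed, and the estimated counts were rounded to whole numbers. Per the file headers, the second deposited table holds FPKM, fragment counts corrected for transcript length and library size. The headers do not say how these values were scaled across libraries. FPKM were used only for alternatives, on the scale of log2(FPKM + 1) or log2(FPKM + 0.1), which understates the change of low genes. The 112 companion columns of variances, confidence bounds and status were not used in any test. The status columns were read to leave out 8 loci, 7 of them named, that the software had marked as holding too many fragments and set to 0.

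The 5143 loci without a gene name, with 3.15% to 6.18% of the counts, stayed out of library sizes and tests. This left 23282 named loci, 397 of them with several symbols joined in 1 locus. A symbol on more than 1 locus was kept as separate loci, described as another locus of that name. The columns name the group but neither the run nor the duplicate. Technical columns were therefore found by agreement within each group, with a chi-square of the counts over expressed genes, whose mean per degree of freedom was 1.64 to 1.88 within pairs and 10.3 to 18.8 between them. The 2 columns of each pair were summed, which gave 8 libraries of 32476669 to 65687420 counts in named genes.

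Genes were tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F-test, TMM normalisation, filterByExpr and Benjamini-Hochberg adjustment over 16130 genes, at an adjusted p under 0.05. All 4 groups were in 1 fit with group as the only term, so that they shared 1 estimate of the spread, with 4 residual degrees of freedom and a common biological coefficient of variation of 12.6%. The 6 comparisons were KO with WT, each rescue with KO and with WT, and the rescues with each other. CPM are counts divided by the TMM-scaled library size, on the usual scale of edgeR.

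The tests, comparisons, gene lists and the rule for named genes were fixed before the data were examined. The rule named Wdr5 and Rax, then the 10 largest increases and decreases among genes past the test at 5 CPM or more in the higher group and with no overlap between replicates (5 of each for the rescues against WT), without unnamed gene models, microRNAs and small nucleolar RNAs, and then up to 4 members of each list with the smallest adjusted p. Sox2 in the T12h rescue against KO and Gata6, Mdm2 and Mest in the T48h rescue against KO fall outside it and were named after their values were seen. Some genes that the rule takes are not reported here. With 2 libraries against 2, chance alone leaves many genes without overlap, so that criterion only removes genes.

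The 26 gene lists had 533 members, all of which were found in the table. They cover the COMPASS/MLL subunits, eye field and retinal progenitor, neural progenitor and postmitotic neuron genes, primitive streak, cardiac and paraxial mesoderm, endothelial and blood, endoderm, trophoblast and neural crest genes. Others are naive pluripotency, general and primed pluripotency, germline, 2-cell-like, p53 target, cytosolic ribosomal protein, Hox, imprinted, hypoxia and glycolysis and stress response genes. The rest are Wnt, BMP and Nodal, and Hedgehog, retinoic acid and Notch targets, cell cycle genes and fibroblast (feeder) markers. Lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01. Benjamini-Hochberg adjustment was over the lists of a comparison. The test was run again with a correlation estimated from the data. In that form camera also uses only the 4 residual degrees of freedom, so a lost call need not reflect correlation between genes. Lists share members, as Otx2 and Tbx3 show.

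Where a group had 0 counts, a fold is a lower bound against 3 counts over the group, which is 0.0285 CPM in the KO, 0.0302 in the T12h rescue, 0.0387 in the T48h rescue and 0.0430 in WT. Where it had 1 to 3 counts, the ratio of CPM is given with its exact 95% counting interval. Intervals and bounds cover counting error only. For overlaps of comparisons that share libraries, unchanged groups were simulated against those libraries 20 times. In them no gene differed between the unchanged groups and the group they were drawn from, so almost no calls could arise.

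The tests were run on simulated counts with known changes in 50 genes at each of 4 sizes. The changed genes all had a mean of at least 50 counts, so the recovery rates do not cover lower genes. At a put-in log2 change of 3 the edgeR test recovered 98% or 100% of the changed genes in each comparison, at 2 it recovered 98%, at 1 between 72% and 90%, and at 0.5 between 32% and 52%. False calls made up 5.6% to 8.5% of all calls, more than the adjusted p of 0.05 aims at. Far fewer genes were moved than the tests called in these data, so neither the recovery rates nor the false-call rates need carry over to them. In the simulation of KO against WT camera ranked the moved list first and called 0 other lists. There the genes were drawn independently and no gene outside the list was moved, so this does not measure false list calls in these data.

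Alternatives were the Wald test of DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, a filter of 5 CPM in 2 libraries, only the 2 groups compared in the fit, limma on FPKM, an estimated correlation and fry for lists, and each library left out in turn. The first or second technical column alone, the counts as deposited and the genes of chromosome 8 left out were added after the data had been seen. Run 1 alone, run 2 alone and a replicate block were not fitted, because no label ties the numbers of the columns to a run or replicate.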

Results

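RNA sequencing was carried out on embryoid bodies, the aggregates that embryonic stem cells form in suspension, at day 6 of differentiation. The mouse embryonic stem cell line carries GFP knocked in at Rx (Rax), a homeobox gene of the eye field. Aggregates were made by SFEBq, a serum-free floating culture with quick reaggregation of dissociated cells, in GMEM with 5% knockout serum replacement. Matrigel, a basement membrane extract, was added at 2% on day 1. The 4 groups were wild type (WT), a Wdr5 knockout clone (KO), and the KO clone in which doxycycline induced human WDR5 from the time points labelled T12h or T48h. They are called the T12h rescue and the T48h rescue below. Wdr5 encodes a WD40-repeat subunit shared by the COMPASS/MLL histone methyltransferase complexes.

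The labels list 16 samples, made up of 2 biological duplicates per group that were each sequenced in 2 technical runs. The column names give the group but neither the run nor the duplicate. Within each group the columns fell into pairs whose counts differed by little more than sampling noise. Their mean chi-square per degree of freedom was 1.64 to 1.88, against 10.3 to 18.8 between columns of different pairs. Each pair was summed and counted as 1 replicate, so n = 2 per group and the replicates are named a and b with no order. The 8 summed libraries held 34730086 and 32476669 estimated fragment counts in named genes for WT. Those of the KO held 65687420 and 35685688, those of the T12h rescue 53298385 and 45208401, and those of the T48h rescue 39762145 and 44661327. Nothing in the labels says that the duplicates came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Levels are CPM, counts scaled to a common library size, as mean ± SD with n = 2, and log2 fold changes are given ± SE from edgeR.

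Wdr5 (chromosome 2, 27515146 to 27536538 on mm10) was measured first, since it checks the labels. It stood at 185.7 and 186.5 CPM in the WT libraries, 32.49 and 28.41 in the KO, 329 and 336.9 in the T12h rescue, and 280 and 293.9 in the T48h rescue. The KO mean was lower than WT by a log2 fold change of -2.61 ± 0.08 (edgeR adjusted p = 2.74e-11). Both rescues stood above WT, by 0.84 ± 0.08 at T12h (edgeR adjusted p = 1.86e-05) and 0.63 ± 0.08 at T48h (edgeR adjusted p = 1.39e-05). The tables hold 1 value per gene, so reads of human WDR5 that aligned to mouse Wdr5 would be counted there. The KO value does not separate the edited locus from the transgene.

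Rax (chromosome 18, 65934638 to 65939089 on mm10) stood at 195 ± 3.2 CPM in WT, 0.788 ± 0.0457 in the KO, 219 ± 5.66 in the T12h rescue and 0.395 ± 0.212 in the T48h rescue (SD, n = 2 each). Reads of the knocked-in allele are part of these values as far as they aligned to Rax. Along the first principal component of log2 CPM, with 47.6% of the variance, the KO libraries stood apart from the other groups. The second, with 37.7%, set the T48h rescue apart, and the third, with 5.05%, separated WT from the T12h rescue.

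**Figure D1:**
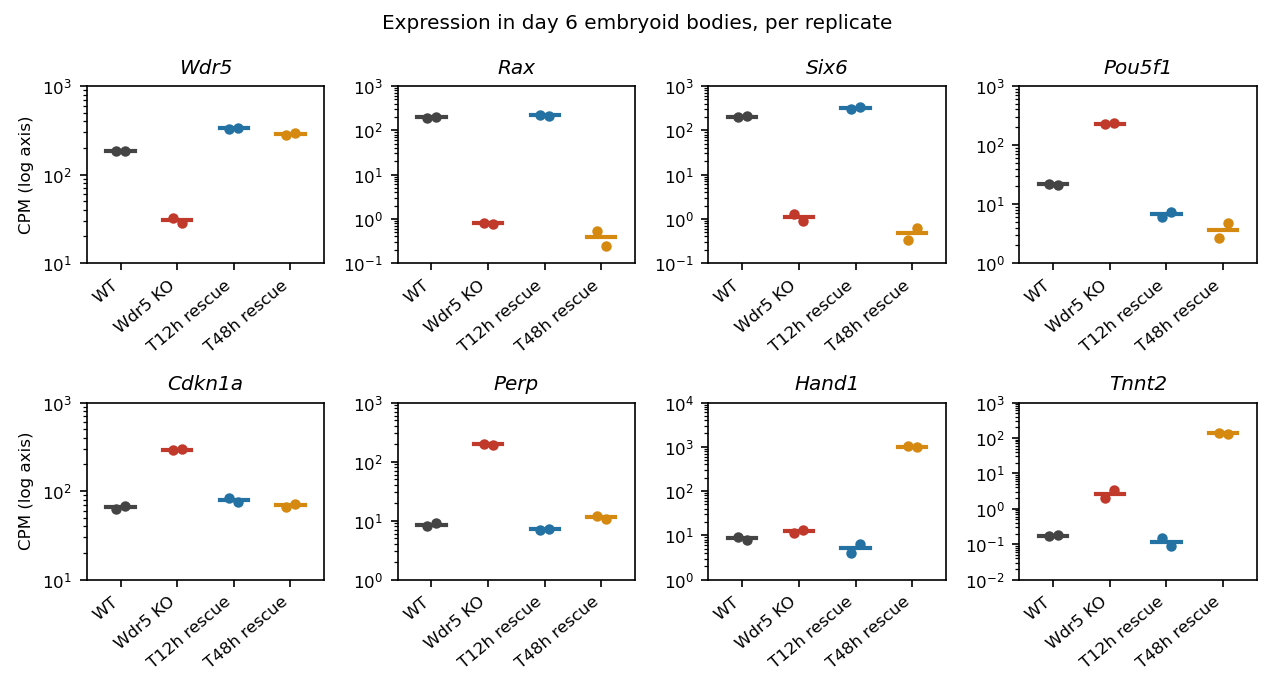
Levels of Wdr5, Rax, Six6, Pou5f1, Cdkn1a, Perp, Hand1 and Tnnt2 in CPM on log axes, by group, with each point a replicate library and each short line the mean of n = 2. Rax has a mean of 195 CPM in WT and 219 in the T12h rescue but 0.788 in the KO and 0.395 in the T48h rescue, while Hand1 reaches 1005 CPM in the T48h rescue.

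The comparison of KO with WT asked what the loss of Wdr5 did at day 6. There was 1 KO clone, so any other difference of that clone from WT enters this comparison too. Transcription factors of the eye field were nearly silent in the KO. Pax6, a master regulator of eye development, fell from 311 ± 30.8 CPM in WT to 1.02 ± 0.406 in the KO (SD, n = 2 each), a log2 fold change of -8.16 ± 0.16 (edgeR adjusted p = 8.85e-13). Rax had a log2 fold change of -7.93 ± 0.14, and Six6, a retinal and hypothalamic homeobox gene, went from 204 to 1.09 CPM. The retinal progenitor gene Nr2e1 and the forebrain gene Fezf1 had log2 fold changes of -7.25 and -7.27. Of the eye field and retinal progenitor list, 16 of 16 tested members fell, with a median log2 fold change of -6.96 (camera adjusted p = 1.5e-09, adjusted p = 0.0858 with an estimated correlation). Among neural progenitor genes 15 of 23 fell and 3 rose (camera adjusted p = 0.00252, adjusted p = 0.235 with an estimated correlation). Pax2 had a log2 fold change of -4.55 ± 0.14, Cdh2, which encodes N-cadherin, of -3.15 ± 0.10, and Sox11 of -2.50 ± 0.08. The largest decreases outside these lists were Rmst, a neural long noncoding RNA, with a WT to KO ratio of 445 with a 95% counting interval of 152 to 2160, the synaptic adhesion gene Nlgn1 at -8.18 and the collagen gene Col9a1 at -7.40.

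Pluripotency genes were higher in the KO. Pou5f1, which encodes Oct4, rose from 21.7 ± 0.401 to 231 ± 4.64 CPM (SD, n = 2 each), a log2 fold change of 3.41 ± 0.16 (edgeR adjusted p = 1.19e-09), and Fgf5, a marker of the primed state, from 2.86 to 90.5 CPM. The naive factors Klf4 and Klf5 rose by log2 fold changes of 2.12 and 2.24. Of the naive list 13 of 15 members rose and 1 fell (camera adjusted p = 2.8e-05, adjusted p = 0.114 with an estimated correlation). The general and primed list had 11 higher and 3 lower of 15 (camera adjusted p = 0.00252, adjusted p = 0.114 with an estimated correlation). Germline genes followed, with 11 of 15 higher and 1 lower (camera adjusted p = 0.00254, adjusted p = 0.114 with an estimated correlation), such as the germ cell helicase Ddx4 at 2.94 ± 0.24. Trophoblast genes had 9 of 12 higher and 0 lower (camera adjusted p = 0.00254, adjusted p = 0.114 with an estimated correlation), with Krt7 at 3.53 ± 0.24 and Gata3 at 3.05 ± 0.23.

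Endoderm, endothelial and primitive streak genes were also higher in the KO, whereas camera called neither the paraxial nor the cardiac mesoderm list. Of the paraxial mesoderm and mesenchyme list 1 rose and 6 fell of 14 (camera adjusted p = 0.169), and of the cardiac list 12 rose and 3 fell of 20 (camera adjusted p = 0.108). The endoderm regulators Sox17 and Gata6 rose by log2 fold changes of 2.90 ± 0.10 and 2.35 ± 0.09. In their list 13 of 20 endoderm genes rose while 5 fell (camera adjusted p = 0.00330, adjusted p = 0.398 with an estimated correlation). Tek, the angiopoietin receptor of endothelium, rose by 4.40 ± 0.12 (edgeR adjusted p = 1.18e-11). In all 8 of 17 endothelial and blood genes rose with 0 lower (camera adjusted p = 0.0331, adjusted p = 0.186 with an estimated correlation). Wnt3, a ligand that the primitive streak requires, rose by 6.82 ± 0.25, whereas the receptor gene Kdr had a log2 fold change of -5.36 ± 0.18. In the list of primitive streak and nascent mesoderm 12 of 18 members rose and 2 fell (camera adjusted p = 0.0374, adjusted p = 0.286 with an estimated correlation). That camera call was lost without WT replicate a (adjusted p = 0.0504), with RLE scaling (adjusted p = 0.0565) and with the first technical column alone (adjusted p = 0.0606), and its adjusted p lay between 0.00121 and 0.286 over all alternatives with camera or fry. The largest increases were in genes with few or no WT counts. They were Clca3, at least 212-fold higher, the lactoferrin gene Ltf, with a KO to WT ratio of 544 with a 95% counting interval of 97.3 to 21490, and Ces2g, which lies on chromosome 8. The others were Sec14l3, Btla, Kcnj15, the keratin gene Krt15, Pamr1, Lhfpl1 and Wnt3.

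Targets of p53 rose in the KO. The cell cycle inhibitor Cdkn1a went from 65.5 ± 3.46 to 291 ± 5.21 CPM (SD, n = 2 each). Mdm2, the ubiquitin ligase that restrains p53, went from 106 ± 4.67 to 473 ± 20.5 CPM. Perp, an apoptosis and adhesion gene, rose by a log2 fold change of 4.51 ± 0.11 (edgeR adjusted p = 5.28e-12) and Plk2 by 2.93 ± 0.09. Of the list 21 of 25 members rose and 1 fell (camera adjusted p = 2.5e-08, adjusted p = 0.114 with an estimated correlation). Hypoxia and glycolysis genes went the other way, with 21 of 23 lower and 1 higher (camera adjusted p = 1.35e-07, adjusted p = 0.0858 with an estimated correlation). The mitophagy gene Bnip3 fell from 92.1 to 11.3 CPM and Vegfa from 139 to 26.9 CPM, while Ndrg1 was the member that rose. Of the cell cycle genes 14 of 20 fell and 2 rose (camera adjusted p = 0.00254, adjusted p = 0.286 with an estimated correlation), with Mki67 at -1.25 ± 0.09 and Aurkb at -1.35 ± 0.07.

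In all, 10337 of 16130 genes tested differed between KO and WT (edgeR quasi-likelihood test, adjusted p under 0.05), 5117 higher and 5220 lower in the KO, or 5460 and 4883 with RLE scaling. At least a 2-fold change was seen in 2889 of the higher and 2525 of the lower genes. On chromosome 8 there were 441 higher and 152 lower genes, against 4676 and 5068 elsewhere. Camera called 12 of the 26 lists, and 0 of them passed with an estimated correlation. The 14 other lists did not pass. They included the subunits of the COMPASS/MLL complexes, 8 higher and 7 lower of 19 (camera adjusted p = 0.955), among which Psip1 had a log2 fold change of -1.06 ± 0.08. Cytosolic ribosomal protein genes, which share reads with pseudogenes, were 17 higher and 23 lower of 79 (camera adjusted p = 0.648). The targets of Hedgehog, retinoic acid and Notch signalling were 6 higher and 5 lower of 17 (camera adjusted p = 0.860). Adjusted over the list alone, the counts of the lists named for KO against WT were the same except neural progenitor (3 higher and 16 lower), endoderm (14 higher and 5 lower), paraxial mesoderm (0 higher and 6 lower), COMPASS/MLL (9 higher and 7 lower) and ribosomal protein (16 higher and 23 lower).

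**Figure D2:**
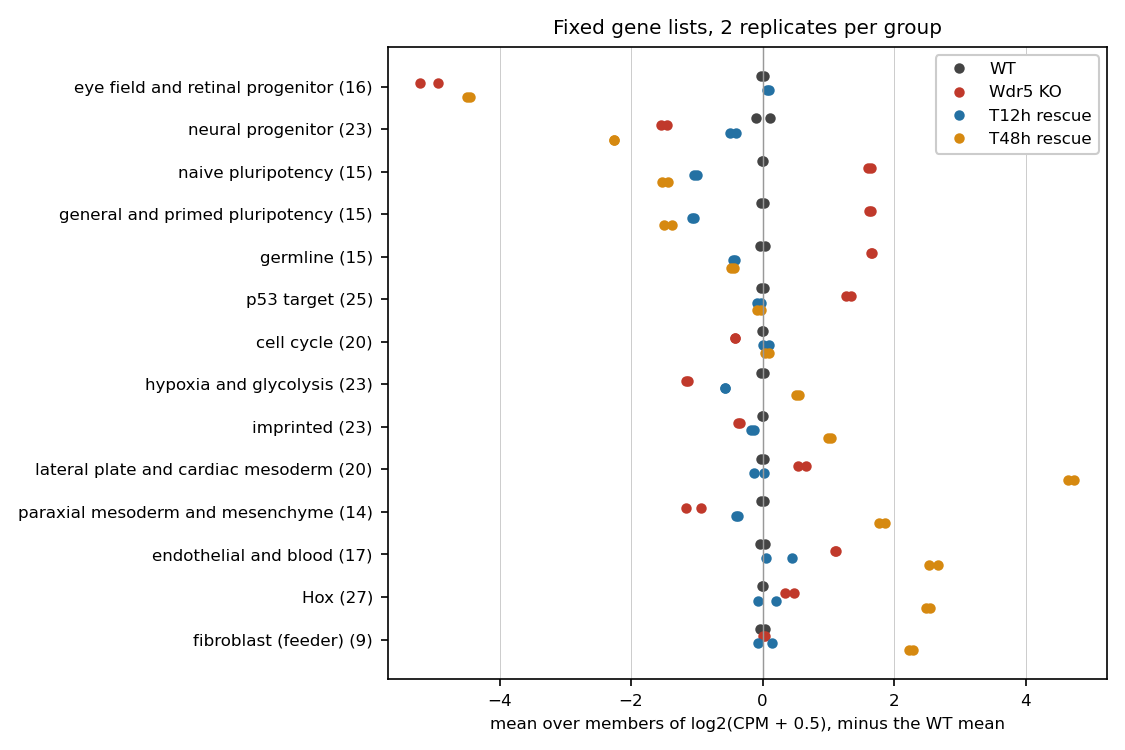
Mean over the members of each fixed gene list of log2(CPM + 0.5) minus the WT mean, with a point for each replicate library and the number of members in brackets. The eye field list lies at -4.93 and -5.21 in the KO libraries, 0.07 and 0.11 in the T12h rescue and -4.45 and -4.50 in the T48h rescue, where the cardiac mesoderm list reaches 4.64 and 4.74.

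The T12h rescue was compared with the KO to see what early induction of WDR5 did. Eye field genes rose from near silence. Rax rose by a log2 fold change of 8.10 ± 0.14 (edgeR adjusted p = 2.9e-13). Six6 rose from 1.09 ± 0.242 to 322 ± 17.8 CPM and Pax6 from 1.02 ± 0.406 to 263 ± 3.00 CPM (SD, n = 2 each). The antisense transcript Six3os1, whose reads cannot be told from those of Six3 without strand, had a log2 fold change of 7.68 ± 0.12. In the list 16 of 16 eye field genes rose (camera adjusted p = 8.76e-09, adjusted p = 0.103 with an estimated correlation). In the next, 14 of 23 neural progenitor genes rose with 5 lower (camera adjusted p = 0.0150, adjusted p = 0.234 with an estimated correlation). Sox3 rose by a log2 fold change of 3.59 ± 0.11. Nkx2-1, a regulator of the ventral forebrain, had a rescue to KO ratio of 1042 with a 95% counting interval of 187 to 41190. Kcnip1, Nlgn1, Nr2e1, Ndnf and Lmo3 were the other large increases, with Ndnf at 7.82 and Lmo3 at 7.66.

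Genes that were high in the KO fell in the T12h rescue. Pou5f1 fell from 231 ± 4.64 to 6.67 ± 0.976 CPM and Fgf5 from 90.5 ± 11.4 to 0.817 ± 0.0292 CPM (SD, n = 2 each). Of the naive list 14 of 15 fell and 1 rose (camera adjusted p = 1.63e-06, adjusted p = 0.103 with an estimated correlation), with Nanog at -3.87 ± 0.16. Of the general and primed list 11 of 15 fell and 3 rose (camera adjusted p = 0.000829, adjusted p = 0.104 with an estimated correlation). Germline genes had 12 of 15 lower and 0 higher (camera adjusted p = 0.000829, adjusted p = 0.103 with an estimated correlation). Trophoblast genes had 10 of 12 lower and 0 higher (camera adjusted p = 0.00245, adjusted p = 0.103 with an estimated correlation). Perp had a log2 fold change of -4.77 ± 0.11 and Mdm2 of -2.31 ± 0.09. In all 22 of 25 p53 targets fell with 1 higher (camera adjusted p = 8.76e-09, adjusted p = 0.103 with an estimated correlation). Nodal, a ligand of the primitive streak, fell from 59.6 to 0.804 CPM, Wnt3 from 39.3 to 0.308 CPM and Eomes from 23.4 to 0.902 CPM. The primitive streak list had 14 of 18 lower and 1 higher (camera adjusted p = 0.00641, adjusted p = 0.192 with an estimated correlation). Lower genes also prevailed in the endoderm list, 12 of 20 with 5 higher (camera adjusted p = 0.0150, adjusted p = 0.480 with an estimated correlation). In the endothelial and blood list 11 of 17 fell with 2 higher (camera adjusted p = 0.0166, adjusted p = 0.152 with an estimated correlation).

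Wnt targets fell in the T12h rescue, 8 of 11 with 2 higher (camera adjusted p = 0.0157, adjusted p = 0.155 with an estimated correlation), such as the feedback inhibitor Dkk1 at -3.57 ± 0.17 and Axin2 at -2.98 ± 0.16. Postmitotic neuron genes had 8 of 15 lower and 2 higher (camera adjusted p = 0.0407, adjusted p = 0.184 with an estimated correlation), with the growth cone gene Gap43 at -4.06 ± 0.16. This camera call was lost without KO replicate b (adjusted p = 0.0572), with RLE scaling (adjusted p = 0.0534) and without the genes of chromosome 8 (adjusted p = 0.0644), and its adjusted p lay between 1.06e-05 and 0.184 over all alternatives with camera or fry. Hypoxia and glycolysis genes rose, 16 of 23 with 3 lower (camera adjusted p = 0.00245, adjusted p = 0.103 with an estimated correlation). So did cell cycle genes, 16 of 20 with 1 lower (camera adjusted p = 0.000614, adjusted p = 0.234 with an estimated correlation). The largest decreases were Mup6, at least 188-fold lower but of a family of near-identical genes and so uncertain, and Nlrp9b, with a KO to rescue ratio of 962 with a 95% counting interval of 266 to 7949. The others were Clca3, Ltf, the keratin genes Krt5 and Krt15, the muscle creatine kinase gene Ckm, Pla2g2f, Ccno and Them5. Between the T12h rescue and the KO 10459 genes differed (edgeR adjusted p under 0.05), 5284 higher and 5175 lower, or 4882 and 5501 with upper-quartile scaling and 4875 and 5518 with RLE scaling. At least a 2-fold change was seen in 2457 and 3129 of them. Camera called 14 lists, and 0 of them passed with an estimated correlation. The counts adjusted over the list alone were the same for the lists named, except neural progenitor (14 higher and 6 lower).

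The T48h rescue was compared with the KO to see what later induction did. Genes of heart and lateral plate mesoderm rose, while the eye field list did not pass the test. Hand1, a transcription factor of cardiac and extraembryonic mesoderm, rose from 12.3 ± 1.31 to 1005 ± 54.5 CPM. The cardiac factor Tbx20 rose from 2.48 ± 0.0345 to 451 ± 24.2 CPM (SD, n = 2 each). Hand2, which lies on chromosome 8, rose by a log2 fold change of 9.03 ± 0.17 (edgeR adjusted p = 9.38e-13), and Mef2c by 7.07 ± 0.16. Nkx2-5, an early cardiac factor, had a rescue to KO ratio of 664 with a 95% counting interval of 183 to 5490. Of the list 18 of 20 members rose and 1 fell, with a median of 5.77 (camera adjusted p = 1.54e-08, adjusted p = 0.0887 with an estimated correlation). In the eye field list 5 members rose and 5 fell of 16 (camera adjusted p = 0.743). Pax6 rose from 1.02 to 10.9 CPM, and Tbx2, also a mesodermal gene, rose by 7.38 ± 0.35. Rax fell further, with a log2 fold change of -1.03 ± 0.29 (edgeR adjusted p = 0.00640), a call that was lost without T48h replicate b (log2 fold change -0.54, edgeR adjusted p = 0.157). Without T48h replicate a the log2 fold change was -1.72, and over all alternatives the edgeR, DESeq2 or limma adjusted p lay between 0.00073 and 0.157.

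Other mesodermal groups rose as well. Paraxial mesoderm and mesenchyme genes had 10 of 14 higher and 1 lower (camera adjusted p = 0.00173, adjusted p = 0.0823 with an estimated correlation), with the collagen gene Col1a1 at 6.56 ± 0.18 and the receptor gene Pdgfrb at 5.29 ± 0.18. Beside them, markers of fibroblasts, the cells used as feeders in stem cell culture, had 5 of 9 higher and 1 lower (camera adjusted p = 0.00840, adjusted p = 0.0887 with an estimated correlation), with the smooth muscle actin gene Acta2 going from 13.8 to 419.5 CPM. Endothelial and blood genes had 11 of 17 higher and 2 lower (camera adjusted p = 0.00940, adjusted p = 0.0887 with an estimated correlation). Tal1, a regulator of blood formation, went from 0.345 to 52.7 CPM, and Fli1, which is not in the list, from 0.0428 to 26.9 CPM. Hox genes, which pattern the body axis behind the forebrain, had 20 of 27 higher and 2 lower (camera adjusted p = 0.00136, adjusted p = 0.239 with an estimated correlation). Hoxb2 rose by 8.49 ± 0.28, Hoxb5 was at least 351-fold higher, and Hoxb6 and Hoxb3 were also among the largest increases. BMP and Nodal targets had 9 of 12 higher and 2 lower (camera adjusted p = 0.00252, adjusted p = 0.0848 with an estimated correlation), with Msx1 at 4.28 ± 0.19 and Nodal itself at -4.86 ± 0.19. Hypoxia and glycolysis genes rose in 20 of 23 cases with 1 lower (camera adjusted p = 5.13e-09, adjusted p = 0.0597 with an estimated correlation). Cell cycle genes rose in 14 of 20 with 3 lower (camera adjusted p = 0.00401, adjusted p = 0.292 with an estimated correlation).

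Pluripotency genes and p53 targets fell in the T48h rescue too. Sox2 went from 122 ± 6.98 to 13.9 ± 0.946 CPM and Pou5f1 to 3.71 ± 1.55 CPM (SD, n = 2 each). Unlike Pou5f1, Sox2 already stood lower in the KO than in WT and was raised by the T12h rescue. The general and primed list had 13 of 15 lower and 1 higher (camera adjusted p = 5.82e-07, adjusted p = 0.0823 with an estimated correlation). The naive list had 13 of 15 lower and 2 higher (camera adjusted p = 0.000194, adjusted p = 0.0887 with an estimated correlation). The germline list had 13 of 15 lower and 1 higher (camera adjusted p = 0.00173, adjusted p = 0.0823 with an estimated correlation). Of the p53 targets 23 of 25 fell and 1 rose (camera adjusted p = 2.63e-09, adjusted p = 0.0823 with an estimated correlation), with Perp at -4.09 ± 0.11. Postmitotic neuron genes had 12 of 15 lower and 2 higher (camera adjusted p = 0.00175, adjusted p = 0.0823 with an estimated correlation). The largest decreases were Aoah, at least 250.4-fold lower, and the gastrokine gene Gkn1, with a KO to rescue ratio of 1220 with a 95% counting interval of 219 to 48210. The others were Gkn2, Gdf3, Btla, Galnt9, Sec14l3, Col6a4, the ligand gene Wnt8a at -8.07, and another locus named Elf3, whose call was lost without KO replicate b (log2 fold change -4.65 in place of -8.50, edgeR adjusted p = 0.0597, against 3.55e-05 to 0.0597 over all alternatives). Hspb7, a small heat shock gene of heart muscle, Nr1h5 and another locus named Rb1 completed the largest increases. In total 10862 genes differed (edgeR adjusted p under 0.05), 5509 higher and 5353 lower, or 4719 and 6141 with upper-quartile scaling. At least a 2-fold change was seen in 2580 and 3362 of them. Camera called 14 lists, and 0 of them passed with an estimated correlation. Adjusted over the list alone, the counts of the lists named for this comparison were the same except endothelial and blood (12 higher and 2 lower), fibroblast (6 higher and 1 lower), hypoxia (21 higher and 1 lower) and germline (2 higher and 13 lower).

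The T48h rescue was set directly against the T12h rescue, which differs from it in the time of induction and with it in the length of exposure to doxycycline. Eye field genes were lower and mesodermal genes higher in the T48h rescue. Rax was lower by -9.13 ± 0.16 (edgeR adjusted p = 2.04e-13). Six3 went from 343 ± 2.37 to 2.55 ± 0.664 CPM, and Aldh1a3, a retinoic acid synthesis gene of the optic vesicle, from 161 ± 5.63 to 0.271 ± 0.00193 CPM (SD, n = 2 each). In the list 15 of 16 eye field genes were lower and 1 was higher (camera adjusted p = 8.09e-10, adjusted p = 0.0293 with an estimated correlation). Of the neural progenitor genes 16 of 23 were lower with 3 higher (camera adjusted p = 3.3e-05, adjusted p = 0.0591 with an estimated correlation). Hand1 went from 5.22 ± 1.87 to 1005 ± 54.5 CPM and Tnnt2, which encodes cardiac troponin T, was higher by 10.10 ± 0.27. The cardiac list had 19 of 20 higher and 0 lower (camera adjusted p = 1.86e-14, adjusted p = 0.0423 with an estimated correlation). The endothelial and blood list had 13 of 17 higher and 2 lower (camera adjusted p = 4.2e-06, adjusted p = 0.0423 with an estimated correlation) and the paraxial list 11 of 14 higher and 0 lower (camera adjusted p = 3.64e-05, adjusted p = 0.0423 with an estimated correlation). Fibroblast markers stood beside them with 7 of 9 higher and 1 lower (camera adjusted p = 3e-04, adjusted p = 0.0545 with an estimated correlation).

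Signalling and axial genes differed between the rescues as well. BMP and Nodal targets had 9 of 12 higher and 1 lower in the T48h rescue (camera adjusted p = 1.19e-05, adjusted p = 0.0423 with an estimated correlation), with Msx2 at 4.17 ± 0.14 and Smad6 at 3.51 ± 0.13. Hypoxia and glycolysis genes had 20 of 23 higher and 1 lower (camera adjusted p = 1.76e-10, adjusted p = 0.0293 with an estimated correlation), with the glucose transporter gene Slc2a1 going from 569 to 1507 CPM. Hox genes had 22 of 27 higher and 0 lower (camera adjusted p = 5.54e-07, adjusted p = 0.0903 with an estimated correlation). Primitive streak genes had 12 of 18 higher and 0 lower (camera adjusted p = 0.000205, adjusted p = 0.0903 with an estimated correlation). Neural crest genes had 9 of 12 higher and 1 lower (camera adjusted p = 0.00165, adjusted p = 0.144 with an estimated correlation), with Snai2 at 6.40 ± 0.21. Stress response genes had 11 of 17 higher and 2 lower (camera adjusted p = 0.0119, adjusted p = 0.15 with an estimated correlation). Trim55, a sarcomere gene, was at least 315-fold higher and the gut hormone gene Pyy at least 209.8-fold higher. The other large increases were Nkx2-5, the endothelial factor gene Erg, Alpk2, Eef1a2, the Nodal co-receptor gene Cfc1, the pericyte gene Rgs5 and Rubie. The largest decreases were Cntn6, Fam181a and Lonrf2, at least 163-fold, 158-fold and 142-fold lower, and Hmx1, with a T12h to T48h ratio of 1887 with a 95% counting interval of 338 to 74550. The others were Vax2 of the ventral retina, from 83.5 to 0.123 CPM, Six6, Aldh1a3, Rax, and other loci named Sox21 and Six6.

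Wdr5 was lower in the T48h than in the T12h rescue, with a log2 fold change of -0.21 ± 0.07 (edgeR adjusted p = 0.0285). The call was lost without T12h replicate b (edgeR adjusted p = 0.06), without T48h replicate a (adjusted p = 0.0806) and with the first technical column alone (adjusted p = 0.0545), within a range of 0.00363 to 0.0806 over all alternatives. Of the genes tested, 8100 differed between the rescues (edgeR adjusted p under 0.05), 4014 higher and 4086 lower in the T48h rescue, or 3439 and 4746 with upper-quartile scaling. At least a 2-fold change was seen in 1774 and 1917. Camera called 13 lists, and 6 of them passed with an estimated correlation. Counts of the lists named in this comparison were all the same when adjusted over the list alone.

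The T12h rescue was set against WT to see how far early induction left the cells from WT. Rax did not pass the test, with a log2 fold change of 0.17 ± 0.09 (edgeR adjusted p = 0.250). Eye field genes went both ways, with 5 higher and 3 lower of 16 (camera adjusted p = 0.0763), a list that passed without WT replicate a (camera adjusted p = 0.0243). Over all alternatives its camera or fry adjusted p lay between 0.017 and 0.409. Otx2 fell from 253 ± 19.7 to 136 ± 3.04 CPM and Vax2 rose from 23.8 ± 3.17 to 83.5 ± 3.36 CPM (SD, n = 2 each). The Vax2 call was lost with DESeq2 (adjusted p = 0.0778, against 4.65e-06 to 0.0778 over all alternatives). Pluripotency genes were below WT. Of the general and primed list 12 of 15 were lower and 0 higher (camera adjusted p = 2.3e-11, adjusted p = 0.0346 with an estimated correlation). Of the naive list 10 of 15 were lower and 0 higher (camera adjusted p = 1.14e-08, adjusted p = 0.0975 with an estimated correlation), with Pou5f1 at -1.71 ± 0.17 and Nanog at -2.02 ± 0.16. Hypoxia and glycolysis genes had 18 of 23 lower and 1 higher (camera adjusted p = 3.25e-14, adjusted p = 0.0235 with an estimated correlation), with Slc2a1 going from 1020 to 569 CPM. Wnt targets had 5 of 11 lower and 0 higher (camera adjusted p = 0.000131, adjusted p = 0.109 with an estimated correlation), with Axin2 at -1.98 ± 0.15.

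Homeobox genes that respond to Hedgehog in the ventral neural tube were among the largest increases of the T12h rescue over WT. They were Nkx2-9, from 0.706 ± 0.135 to 6.61 ± 1.28 CPM (SD, n = 2 each), and Nkx2-2 and Nkx2-1, with log2 fold changes of 2.78 ± 0.38 and 2.07 ± 0.36. The fixed list of Hedgehog, retinoic acid and Notch targets was not called, with 5 higher and 3 lower of 17 (camera adjusted p = 0.180). The imprinted noncoding RNA Peg13, which lies within Trappc9, was 4.30-fold higher. Rps28, which shares reads with pseudogenes, had a log2 fold change of 2.41 ± 0.52 (edgeR adjusted p = 0.00718). The call was lost without WT replicate a (log2 fold change 1.71, edgeR adjusted p = 0.05) or T12h replicate a (adjusted p = 0.0702), and the log2 fold change was 3.79 without WT replicate b. Over all alternatives its edgeR, DESeq2 or limma adjusted p lay between 4.07e-05 and 0.0702. The largest decreases were the dynein gene Dnahc10 at -6.79 ± 0.48, the Wnt agonist gene Rspo3 at -3.68 ± 0.24, Samd5 at -3.07 ± 0.25, the forebrain ligand gene Wnt8b at -3.04 ± 0.29, and Tuba3a, which has near-identical copies and is uncertain. Among smaller list calls, endoderm had 8 of 20 higher and 1 lower (camera adjusted p = 0.00951, adjusted p = 0.507 with an estimated correlation) and postmitotic neuron 4 of 15 lower and 0 higher (camera adjusted p = 0.00956, adjusted p = 0.146 with an estimated correlation). Stress response had 6 of 17 lower and 2 higher (camera adjusted p = 0.00771, adjusted p = 0.221 with an estimated correlation) and neural crest 6 of 12 lower and 2 higher (camera adjusted p = 0.0287, adjusted p = 0.348 with an estimated correlation). Ribosomal protein genes had 18 of 79 lower and 7 higher (camera adjusted p = 0.0287, adjusted p = 0.507 with an estimated correlation). Of 9 2-cell-like genes 0 passed the gene test in either direction, with a median of -1.86 (camera adjusted p = 0.00678, adjusted p = 0.146 with an estimated correlation). Of these camera calls, endoderm was lost without WT replicate b (adjusted p = 0.051) or T12h replicate b (adjusted p = 0.0941). Ribosomal protein was lost without WT replicate b (adjusted p = 0.722) or T12h replicate a (adjusted p = 0.118) and neural crest without T12h replicate a (adjusted p = 0.058). Over all alternatives the camera or fry adjusted p of endoderm lay between 5.34e-05 and 0.507, of ribosomal protein between 5.17e-06 and 0.722, of neural crest between 0.0166 and 0.348, and of the 2-cell-like list between 0.00215 and 0.146. With the first technical column alone the neural crest and 2-cell-like lists were not called (camera adjusted p = 0.114 each). On the summed libraries, fry did not call the endoderm and ribosomal protein lists (fry adjusted p = 0.103 and 0.183).

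Genes of chromosome 8 stood above WT in the T12h rescue. Of 852 tested genes there, 459 were higher and 12 lower, against 816 higher and 974 lower elsewhere. Thus 55.3% of its genes differed and 11.7% of the others. The median log2 fold change of its genes at 5 CPM or more lay above that of the other chromosomes by 0.50 in the T12h rescue, 0.47 in the KO and 0.46 in the T48h rescue. Single libraries of the KO clone lay at 0.43 to 0.51 and the WT libraries within 0.003 of 0. Other whole chromosomes lay between -0.065 and 0.032 in the T12h rescue, -0.138 and 0.082 in the KO, and -0.068 and 0.063 in the T48h rescue. Along chromosome 8, median log2 fold changes against WT in 13 bins of 10 Mb were 0.37 to 0.59 in the T12h rescue, 0.10 to 0.79 in the T48h rescue and -0.36 to 0.60 in the KO, where 5 bins were under 0.1. In 236 bins of other chromosomes the medians were 0.00, 0.01 and -0.13 (SD 0.068, 0.124 and 0.237) in these groups, and 13, 13 and 12 of the chromosome 8 bins lay above them. Against the KO the shift was 0.04 in the T12h and -0.07 in the T48h rescue.

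**Figure D3:**
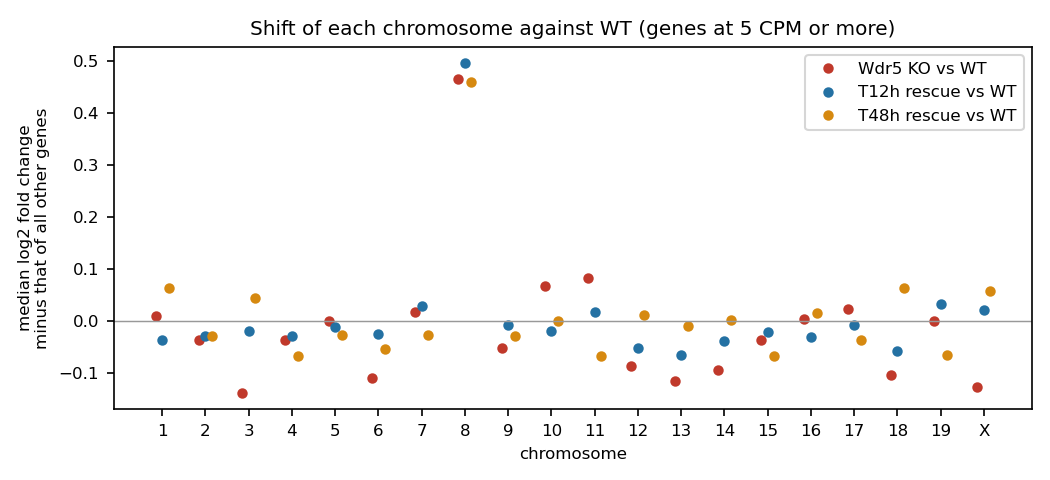
Shift of each chromosome's median log2 fold change against WT relative to all other genes at 5 CPM or more, with a point each for the KO, the T12h rescue and the T48h rescue. Chromosome 8 lies at 0.47, 0.50 and 0.46 in the 3 groups.

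Over all chromosomes 2261 genes differed between the T12h rescue and WT (edgeR adjusted p under 0.05), 1275 higher and 986 lower. With upper-quartile scaling more were lower, 1195 against 1047 higher. At least a 2-fold change was seen in 131 and 404. Without WT replicate a the count was 1070, without T12h replicate a 1217, and without T12h replicate b 1316. It was 1437 with limma on log2(FPKM + 1) and no filter, and 1623 (795 higher, 828 lower) without the genes of chromosome 8. Camera called 10 lists, of which the general and primed pluripotency list and the hypoxia list passed with an estimated correlation. Adjusted over the list alone, the counts were eye field 8 higher and 5 lower, general and primed pluripotency 0 higher and 13 lower, naive pluripotency 1 higher and 14 lower, and hypoxia 1 higher and 19 lower. They were Wnt targets 1 higher and 7 lower, endoderm 9 higher and 2 lower, stress response 2 higher and 7 lower, neural crest 2 higher and 8 lower, Hedgehog, retinoic acid and Notch targets 6 higher and 4 lower and ribosomal protein 8 higher and 20 lower, with the other named lists the same.

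The T48h rescue against WT showed the mesodermal genes high and the eye field genes low. Hand1 rose from 8.53 ± 1.15 to 1005 ± 54.5 CPM and Col1a1 from 4.26 ± 1.32 to 553 ± 65.2 CPM (SD, n = 2 each). Tek rose from 2.58 ± 0.242 to 182 ± 17.2 CPM, while Rax had a log2 fold change of -8.96 ± 0.16. The cardiac list had 19 of 20 higher and 0 lower (camera adjusted p = 1.67e-14, adjusted p = 0.0419 with an estimated correlation). The endothelial and blood list had 12 of 17 higher and 0 lower (camera adjusted p = 3.51e-06, adjusted p = 0.0404 with an estimated correlation). The paraxial list had 10 of 14 and 1 (camera adjusted p = 0.000133, adjusted p = 0.0419 with an estimated correlation). Fibroblast markers stood beside them with 7 of 9 higher and 0 lower (camera adjusted p = 2e-05, adjusted p = 0.0404 with an estimated correlation). BMP and Nodal targets had 8 of 12 higher and 1 lower (camera adjusted p = 2e-05, adjusted p = 0.0404 with an estimated correlation). Hypoxia and glycolysis genes had 17 of 23 and 1 (camera adjusted p = 1.44e-05, adjusted p = 0.0404 with an estimated correlation). Eye field genes had 15 of 16 lower and 1 higher (camera adjusted p = 5.73e-11, adjusted p = 0.0404 with an estimated correlation). Neural progenitor genes had 17 of 23 lower and 1 higher (camera adjusted p = 2.14e-07, adjusted p = 0.0580 with an estimated correlation). Hox genes had 21 of 27 higher and 0 lower, with a median of 6.04 as fitted and 5.38 with members at 0 counts in a group set to their bound (camera adjusted p = 3.01e-06, adjusted p = 0.114 with an estimated correlation).

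Pluripotency genes were below WT in the T48h rescue, 9 of 15 in the general and primed list with 2 higher (camera adjusted p = 0.000664, adjusted p = 0.0674 with an estimated correlation). In the naive list 12 of 15 were lower and 2 higher (camera adjusted p = 0.00187, adjusted p = 0.141 with an estimated correlation). Sox2, which unlike Pou5f1 also stood below WT in the KO, fell from 304 ± 6.06 to 13.9 ± 0.946 CPM (SD, n = 2 each). Primitive streak genes had 12 of 18 higher and 0 lower (camera adjusted p = 0.000607, adjusted p = 0.114 with an estimated correlation). Endoderm genes had 10 of 20 higher and 3 lower (camera adjusted p = 0.0168, adjusted p = 0.430 with an estimated correlation). Postmitotic neuron genes had 7 of 15 lower and 1 higher (camera adjusted p = 0.0455, adjusted p = 0.142 with an estimated correlation). This camera call was lost in 5 of the 8 fits without a library, those without WT replicate a (adjusted p = 0.0645), KO replicate a (0.055), T12h replicate a (0.0541), T12h replicate b (0.0545) or T48h replicate b (0.0634). It was also lost without the genes of chromosome 8 (camera adjusted p = 0.103) and with the second technical column alone (0.062), and its adjusted p lay between 4.73e-05 and 0.142 over all alternatives with camera or fry. The largest increases were Hoxb6, Hspb7 and Oit3, at least 327-fold, 232-fold and 222-fold higher, and the endothelial receptor gene Tie1, with a rescue to WT ratio of 1623 with a 95% counting interval of 449 to 13410. Alpk2 was next. The largest decreases were Rmst, Cntn6 and Fam181a, at least 327-fold, 301-fold and 140-fold lower, another locus named Sox21, and Hmx1. In total 7627 genes differed (edgeR adjusted p under 0.05), 3858 higher and 3769 lower. At least a 2-fold change was seen in 1527 and 2006, and on chromosome 8 there were 434 higher and 103 lower. With upper-quartile scaling the split was 3053 higher and 4791 lower. Camera called 15 lists, and 8 of them passed with an estimated correlation. For the lists named in this comparison, the counts adjusted over the list alone were the same except BMP and Nodal (9 higher and 2 lower) and hypoxia (18 higher and 1 lower).

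How much of the KO change each rescue turned back was counted over the 10337 genes that differed between KO and WT. In the T12h rescue 8885 of them, 86.0%, changed in the opposite direction against KO, among them Rax, Pax6, Pou5f1 and Perp. Another 75 changed further in the KO direction. Of the 8885, 7522 no longer passed the test against WT, and 1363 still differed, 616 on the KO side of WT and 747 past it. In the T48h rescue 7402, or 71.6%, were turned back, Perp and Pou5f1 among them, and 863 moved further, Rax among them. There 4164 no longer passed the test against WT, and 3238 still differed, 1322 on the KO side and 1916 past WT. The overlap of independent lists would be 3352 genes for T12h and 3481 for T48h. Unchanged groups simulated against the shared KO libraries gave a median of 0, with at most 2 for T12h and 1 for T48h in 20 simulations. No gene differed between rescue and KO in those simulations, so almost no calls could arise. These counts therefore do not measure what the shared libraries add. Part of the excess over independent lists may come from the shared KO libraries, and no split was made, since each side would hold 1 KO library. Without WT replicate a, WT replicate b, T12h replicate a or T12h replicate b, the T12h count that still differed from WT was 621, 809, 673 or 743.

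Against KO, 8294 genes passed the test in both rescues, 3744 of them higher and 3647 lower in both. Independent lists would share 1805 and 1717. Simulated unchanged groups shared a median of 0 and at most 1, but in them no gene differed from the KO, so almost no calls could arise. Pou5f1, Perp and Mdm2 were lower, and Mest, an imprinted gene, was higher in both. Mest stood at 635 ± 7.10 CPM in the KO, 5287 ± 218 in the T12h rescue and 2485 ± 11.4 in the T48h rescue (SD, n = 2 each). Of the 4553 genes that were lower in the KO and raised by the T12h rescue, 1742 were lower and 907 higher in the T48h than in the T12h rescue. Of the 4332 that were higher in the KO and lowered by the T12h rescue, 1528 were higher and 854 lower in the T48h rescue.

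**Figure D4:**
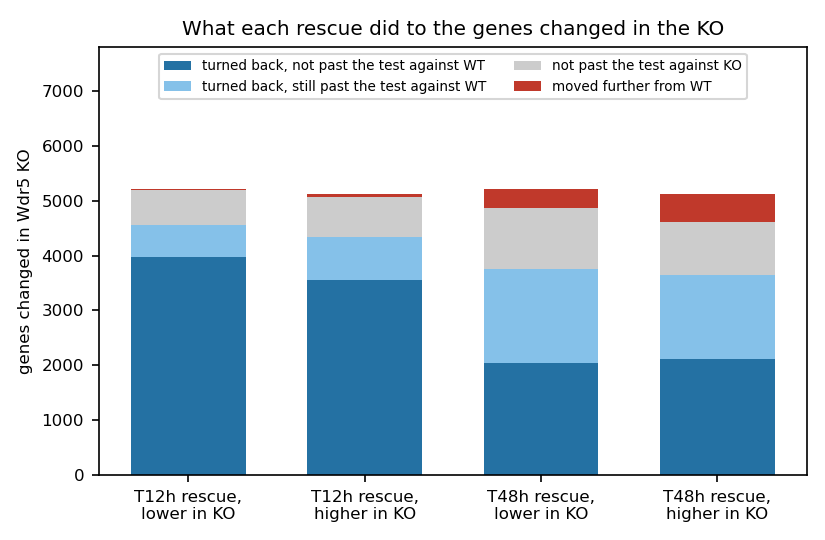
Number of genes changed in the KO, split into those lower and those higher than WT and shown for each rescue as stacked bars of what the rescue did against KO and against WT. Among genes lower in the KO 3965 were turned back and no longer past the test against WT in the T12h rescue and 2041 in the T48h rescue, and among genes higher in the KO 3557 and 2123.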

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

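The comparisons, the gene lists, the fits without a library and the tests of scaling and of a chromosome gain were set before their results were seen, and the other tests of explanations were chosen after.

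The rescues changed 903 genes in opposite directions against KO, which by itself sets these genes apart between the rescues. Of them 377 were raised by the T12h rescue and lowered by the T48h rescue, Sox2 among them, and 526 went the other way, Gata6 among them. In the loci without a gene name, which no comparison of named genes used, 373 of 4031 tested were higher and 659 lower in the KO than in WT by edgeR. There were 285 such loci higher and 287 lower in the T48h rescue than in WT.

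Wdr5 counts in the KO libraries stood at a mean of 30.5 CPM, or 16.4% of WT. Wild-type cells mixed into the KO cultures would bring every WT transcript in at that share, but 126 genes at 20 CPM or more in WT lay in the KO at a share clearly below that of Wdr5, with Rax at 0.405% of WT. This argues against mixed cultures as the source of all the Wdr5 counts. Transcript from the edited locus may account for the 30.5 CPM, and so may the transgene without doxycycline. These cannot be told apart, because the tables hold neither exon counts nor human-specific bases.

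The T48h rescue had 15 of 16 eye field genes lower and 19 of 20 cardiac mesoderm genes higher than the T12h rescue. Feeder fibroblasts could bring mesenchymal transcripts, and 7 of 9 fibroblast markers were higher with 1 lower (camera adjusted p = 3e-04, adjusted p = 0.0545 with an estimated correlation), but to dilute Rax by a log2 fold change of -9.13 they would have to be nearly all of the culture, while the highest of their markers Dcn, Lum and Thy1 reached 1.35 CPM, which argues against them as the whole source. Another scaling moved either list's median by at most 0.0849 on the log2 scale, which argues against scaling. An effect of doxycycline that grows with exposure would place the T48h rescue between KO and the T12h rescue, but 17 of 20 cardiac genes were above both, while for the eye field genes as a set, of which 5 were below KO and 5 above it, length of exposure and time of induction cannot be told apart, because they change together. The time at which WDR5 was induced, which the design names, stays open as a hypothesis and was not tested apart from exposure.

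The 2261 genes that differed between the T12h rescue and WT, a count of 1070 without WT replicate a, 1217 without T12h replicate a and 1316 without T12h replicate b, had several candidate sources. A part of the KO change left behind would place genes on the KO side of WT, but of 1790 such genes outside chromosome 8, 651 (36.4%) lay past the test on the other side of WT in the KO and 787 on the same side, so it is not the whole source. A gain of chromosome 8 in the KO clone, a hypothesis as no DNA was measured, was the prediction that the values met, since its median stood above the other chromosomes in all 3 groups of the clone by at least 0.461 on the log2 scale, against 0.585 for 3 copies in place of 2, although in the KO 5 of its 13 bins of 10 Mb were under 0.1 and 12 above the median of other bins (-0.13, SD 0.237). Outside chromosome 8, 362 genes were on the same side of WT in the KO and both rescues, against 133 for independent lists. Another 341 were on the same side in both rescues but not in the KO, against 283. Unchanged groups simulated 20 times against the same WT libraries gave 0 each time. No gene differed in those simulations, so the test had almost nothing to call. The 0 therefore does not measure what the shared libraries add. Part of either excess may come from the shared WT libraries, and another difference of the clone, or doxycycline, which WT did not receive, cannot be told apart from effects of WDR5, because there was 1 clone and no WT with doxycycline.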

How the results depend on the processing

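The alternatives with a single technical column, with the counts as deposited and without chromosome 8 were chosen after the data had been seen, and the others before. In each fit without a library, the lone remaining library of its group is assumed to vary like the other groups.

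Counts of changed genes stayed within 1.5 times the reported count under every alternative that keeps all libraries, except the T12h rescue against WT with limma on log2(FPKM + 1) and no filter, which gave 1437 in place of 2261 while testing 19847 genes. Without 1 library the counts were 8500 to 10584 for KO against WT, 8853 to 10819 for the T12h rescue against KO, 9857 to 10627 for the T48h rescue against KO, 6229 to 8153 between the rescues, 1070 to 2571 for the T12h rescue against WT and 5780 to 7673 for the T48h rescue against WT. The low values for the T12h rescue against WT were 1070 without WT replicate a, 1217 without T12h replicate a and 1316 without T12h replicate b. Genes turned back numbered 7667 to 9129 for T12h and 6221 to 7182 for T48h. Those turned back that still differed from WT were 621 to 1576 for T12h, with 621 without WT replicate a, 809 without WT replicate b, 673 without T12h replicate a and 743 without T12h replicate b, and 2255 to 3050 for T48h. For counts that fell without a library, the fit has fewer samples, and no further cause was tested.

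List calls differed between camera with the preset correlation of 0.01 and camera with an estimated one. The losses did not follow the size of the correlation alone. In KO against WT, the hypoxia, trophoblast and germline calls were lost although their estimates, -0.0158, -0.0734 and -0.0413, lay below the preset value. Other lost calls had higher estimates, such as eye field at 0.0561. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom, whereas with a preset one it draws on far more. These values therefore also carry the small number of libraries, and how much each part adds was not tested. With an estimated correlation, 0, 0, 0, 6, 2 and 8 lists passed in KO against WT, T12h against KO, T48h against KO, T48h against T12h, T12h against WT and T48h against WT, in place of 12, 14, 14, 13, 10 and 15. Fry, which does not compare a list with other genes, called 20, 23 and 24 lists in the first 3 comparisons. Without 1 library the numbers were 11 to 12, 13 to 14, 14 to 15, 14 to 15, 8 to 12 and 14 to 16. The primitive streak list in the T48h rescue against KO, not called by camera, was called by fry in the other direction (adjusted p = 0.0181, against 0.86 to 0.999 with camera), and the cause was not tested. Upper-quartile scaling moved the median of all genes by -0.144 in the T48h rescue against KO and by -0.124 against WT, where the split became 3053 higher and 4791 lower. The same scaling gave fewer higher than lower genes in T12h against KO (4882 and 5501), T48h against KO (4719 and 6141), T48h against T12h (3439 and 4746) and T12h against WT (1047 and 1195), and more in KO against WT (5241 and 5114). With RLE the splits were 5460 and 4883 in KO against WT, 4875 and 5518 in T12h against KO, 5196 and 5623 in T48h against KO and 4100 and 4015 between the rescues, each turned from the one with TMM, as they were with DESeq2. No list called by camera changed the sign of its median under RLE, upper-quartile or DESeq2 scaling.

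Of 188 gene values named in the text, 183 kept their direction and their side of the threshold in every alternative run for single genes. With limma on log2(FPKM + 1) only 184 of the 188 had a value. The exceptions, none reversed, were Rax and another locus named Elf3 in the T48h rescue against KO, Wdr5 between the rescues, and Rps28 and Vax2 in the T12h rescue against WT, with 6 lost calls without a library, 1 with DESeq2 and 1 with a single technical column. The lists had 78 calls. Counted per list and alternative, 72 calls were lost and 47 gained over alternatives that keep all libraries, 62 of the losses with an estimated correlation and 43 of the gains with fry. Without a library 12 were lost and 21 gained.

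Run 1 only, run 2 only and the replicate block were not run. No paired analysis was possible because the columns carry no replicate number. Depth limits genes near the floors of 0.0285 to 0.0430 CPM over a group.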

Other observations

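Both lists of dorsal and ventral genes below were written after the T12h rescue had been compared with WT, and their prediction was written before their own values were seen.

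Imprinted genes, which are expressed from the allele of a single parent and many of which act in growth, rose in the T48h rescue. Of 23 genes 15 were higher and 5 lower than in the KO (camera adjusted p = 0.000779, adjusted p = 0.0823 with an estimated correlation), 14 and 4 against the T12h rescue (camera adjusted p = 0.000337, adjusted p = 0.0508 with an estimated correlation), and 16 and 3 against WT (camera adjusted p = 1.29e-05, adjusted p = 0.0404 with an estimated correlation). The counts adjusted over the list alone were the same, except 18 higher and 3 lower against WT. Peg3 stood at 651 ± 40.2 CPM in WT, 1330 ± 13.9 in the KO, 823 ± 20.4 in the T12h rescue and 6739 ± 1.12 in the T48h rescue (SD, n = 2 each). Markers of other cell types moved in the same comparison of the rescues, with cardiac genes 19 of 20 higher, paraxial 11 of 14 and fibroblast 7 of 9 in the T48h rescue. The noncoding RNA H19 went from 651 ± 22.6 CPM in the T12h to 6191 ± 390 in the T48h rescue, a log2 fold change of 3.25 ± 0.11 (edgeR adjusted p = 3.32e-11). Phlda2, a placental growth regulator, went from 1.03 ± 0.0163 to 169.7 ± 26.6 CPM and Usp29 from 38.1 ± 1.98 to 235 ± 3.97 CPM. In KO against WT the list was mixed, 9 higher and 10 lower of 23 (camera adjusted p = 0.648), with Dlk1 at -3.90 ± 0.17 and Peg10 at 1.69 ± 0.07.

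The T12h rescue had Nkx2-9, Nkx2-2 and Nkx2-1 above WT and Wnt8b below it. The Hedgehog target Gli1 was also higher, at 15.4 ± 0.248 CPM in WT and 37.8 ± 4.13 in the T12h rescue (SD, n = 2 each; edgeR adjusted p = 7.66e-05). The fixed list of Hedgehog, retinoic acid and Notch targets was mixed, 5 higher and 3 lower of 17 (camera adjusted p = 0.180, adjusted p = 0.368 with an estimated correlation). A hypothesis is that its neural progenitors may be more ventral than those of WT. Of 15 dorsal genes tested 0 were higher and 9 lower than WT, with Rspo2 at 9.02 CPM in WT and 1.43 in the T12h rescue and Wnt3a at 1.32 and 0.153 (camera p = 7.78e-06 over the dorsal list, p = 0.0248 with an estimated correlation). Of 12 ventral genes 4 were higher and 3 lower (camera p = 0.0629, and 0.267 with an estimated correlation), with Foxd1 at 18.5 and 57.8 CPM, Ntn1 at 69.6 and 111 and Slit1 at 1.41 and 0.503. Without the 3 members that also belong to fixed lists, the ventral list had 3 higher and 3 lower of 9 (camera p = 0.466, and 0.553 with an estimated correlation). The dorsal part of the prediction was met and the ventral part was not, so the hypothesis stays open, and a loss of dorsal genes without a gain of ventral ones would also give these values.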
